A study of Cucumis sativus with 4 samples.

How the data were processed

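Total RNA from the first true leaf was made into libraries by standard Illumina methods and sequenced, per the labels' protocols, in 2 wild type (empty vector) and 2 CsTCP18a-RNAi libraries of cucumber. Plants grew with 16 h of light at 25 °C and 8 h of dark at 18 °C. TopHat, a spliced read aligner, and HTSeq, a read counter, are named without versions in the submitters' processing notes. The genome build, the strand setting of the counting and the statistical test of the authors are not given in the sources used here. If the counting ignored strand, reads of overlapping genes on opposite strands cannot be told apart. Reads shared by near-identical gene copies may be lost or split by the counting.

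The authors deposited 1 table with 1 column per library and a normalised signal per gene, which the table's name calls CPM. The columns total 1209165.3 and 1083973.9 in wild type replicates 1 and 2, and 869612.6 and 877343.5 in RNAi replicates 1 and 2, so the values are not plain CPM. Each column proved to hold whole multiples of 1 step, which gave the deposited values back as whole reads: 100% of values in each library were whole to within 0.01 read. TMM factors computed from these reads with edgeR were 0.827, 0.9225, 1.1499 and 1.1398 for wild type 1, wild type 2, RNAi 1 and RNAi 2, and matched the factors that the column totals imply to 4 decimals. The values are therefore called normalised CPM here: CPM computed on the TMM-scaled library size. Every gene in the table has at least 1 CPM in 2 libraries (the smallest second-highest value is 1.004), so scarce transcripts outside the table are not analysed here. All 4 columns were matched to samples by their names.

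The main test, fixed before the data were examined, was limma (version 3.58.1, in R 4.3.3) with a mean-variance trend on log2(normalised CPM + 1), without further scaling and without a replicate block. Genes with at least 1 normalised CPM in at least 2 libraries were tested, 17491 in all. Benjamini-Hochberg adjusted p under 0.05 counted as a call. That plan assumed CPM. The TMM scaling of the deposited values changed neither the test nor its settings. The table pairs no names with its IDs. None of the 17585 IDs matched the RefSeq gene table for assembly Cucumber_9930_V3, also after removing punctuation from the IDs, and no coordinates from that table were used. As a consequence 0 of the 39 gene lists and marker lists planned on gene names were tested, and the values of CsTCP18a were not analysed here. The rule fixed for unnamed IDs was to give at most 2 that rose and 2 that fell, those with the largest change among genes that passed. The classes of abundance, the near-silent genes (at least 10 in one group, under 0.5 in both libraries of the other), the ID prefixes and the ranking of abundant genes were chosen after the values were seen.

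Alternatives were other pseudocounts, other filters, other scalings, a replicate block, each library left out, limma without a trend, and count models on the recovered reads with edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0). A few settings were added after seeing the data: plain CPM, reads thinned to equal depth, removal of the 100 most abundant genes, and a spread estimated per group.

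The test was tried on simulated counts with the library sizes and means of the real libraries and 50 genes changed by each of several known folds. With a spread that differed from gene to gene, limma on 17302 genes recovered 0 of 50 genes changed 1.5-fold, 16 of 50 changed 2-fold, 45 of 50 changed 4-fold and 50 of 50 changed 8-fold, and 33 of its 144 calls (22.9%) were unchanged genes. With a spread set by abundance alone, 6 of 131 calls (4.58%) were unchanged genes. With the measured fold changes and 40 percent of genes set to no change, 98 of 5165 calls (1.90%) among 16988 genes were unchanged genes. Each simulation gave both groups the same spread, whereas the real wild type libraries differed from each other more than the RNAi libraries did. The real test also called 10592 of 17491 genes. For both reasons these recoveries and shares need not carry over to the real calls. A gene without a call may thus still differ, even by 2-fold. One read is worth 0.0437, 0.0573, 0.0357 and 0.0319 normalised CPM in wild type 1, wild type 2, RNAi 1 and RNAi 2. Intervals of read ratios and the floors cover counting error only, whereas the confidence intervals of log2 fold changes come from limma and the spread between libraries.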

Results

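RNA sequencing compared the first true leaf of cucumber (Cucumis sativus) seedlings carrying an RNA interference construct against CsTCP18a with that of control seedlings transformed with the empty vector, which the labels call wild type. CsTCP18a belongs to the TCP family of plant transcription factors and is related to BRANCHED1, a gene known from other plants to restrain the outgrowth of axillary buds. The construct carried a 402-bp fragment of the CsTCP18a coding sequence, and leaves were taken from plants 20 days old. Each group held 2 libraries. The recovered gene-assigned reads numbered 27664402 and 18930131 in wild type replicates 1 and 2, and 24372389 and 27507543 in RNAi replicates 1 and 2. The table held 17585 genes, of which 17491 entered the test. The labels do not say whether the 2 libraries of a group came from separate plants or separate transgenic lines, so the p-values measure only the spread between these libraries, which may be technical.

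The comparison asked which leaf transcripts differed between plants in which CsTCP18a was targeted and control plants. The deposited table carried locus IDs without gene names, and 0 of its 17585 IDs could be paired with a name in the cucumber gene table used here. The level of CsTCP18a itself was therefore not analysed here, and no check of the silencing or of the genotype labels was made from the transcript values. Genes are described below by ID, by abundance and by the pattern of their change.

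Transcript levels differed between the groups across most of the measured genes. In limma's moderated test, 5427 genes (31.0%) were higher and 5165 genes (29.5%) were lower in the RNAi libraries at a Benjamini-Hochberg adjusted p under 0.05, and 6899 genes (39.4%) did not pass. The median change was 1.31 on the log2(CPM + 1) scale among the higher genes and -1.22 among the lower genes. On this scale, which understates changes of scarce transcripts, at least a 2-fold change of CPM + 1 was seen in 3519 higher and 3146 lower genes. A change of CPM + 1 of at least 16-fold was seen in 367 higher and 202 lower genes. The wild type and RNAi values did not overlap for 14620 genes (83.6%). For a single gene, chance alone gives 33.3% for 2 libraries against 2, provided that all libraries vary alike. The wild type libraries varied more than the RNAi libraries, and all genes share the same libraries. The 33.3% is therefore no benchmark for the count of genes without overlap. For 6754 genes (38.6%) the 95% confidence interval of the log2 fold change lay within 1 unit of 0, and for 1380 genes it lay within 0.5. When either RNAi library was left out, the higher calls fell to 2242 (without replicate 1) or 2368 (without replicate 2) and the lower calls to 1854 or 2055. The split into higher and lower depended on the scaling: with plain CPM in place of the deposited TMM-scaled values, 7534 genes were higher and 3477 lower, and the median log2 fold change of all genes moved from 0.03 to 0.38.

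**Figure D1:**
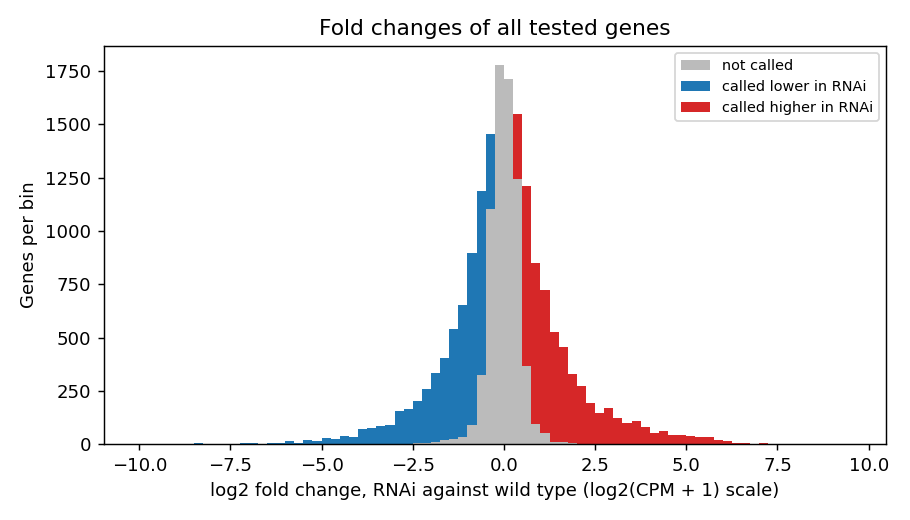
Histogram of the log2 fold change of RNAi against wild type for the 17491 tested genes in bins of equal width, stacked by outcome of limma's test. The 5427 higher genes have positive and the 5165 lower genes negative changes. The 6899 genes that did not pass overlap both in the size of the change. A change of CPM + 1 of at least 16-fold was seen in 367 higher and 202 lower genes. With plain CPM the calls are 7534 higher and 3477 lower.

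The IDs with the largest increases and decreases were scarce in one group and abundant in the other. Csa6G514850 had 454 ± 28.5 normalised CPM in RNAi leaves and 0.0723 ± 0.0213 in wild type leaves (SD, n = 2 each). Csa3G026690 had 378 ± 4.30 normalised CPM in RNAi leaves and 0.0437 ± 0.0618 in wild type. Only 3 and 2 reads, respectively, stood behind the wild type values, so the ratio of RNAi to wild type was 6096 (95% counting interval 2086 to 29560) for Csa6G514850 and 7622 (2110 to 62940) for Csa3G026690. In the other direction, Csa3G105950 had 2838 ± 438 normalised CPM in wild type and 3.18 ± 0.915 in RNAi leaves, a ratio of wild type to RNAi of 869 (754 to 1007). Csa4G285740 had 363 ± 7.92 normalised CPM in wild type and 0.114 ± 0.110 in RNAi leaves, a ratio of 3086 (1498 to 7678) that rests on 7 RNAi reads. On the log2(CPM + 1) scale, which understates changes that start near 0, the changes were 8.73 (SE 0.13), 8.51 (SE 0.13), -9.42 (SE 0.20) and -8.36 (SE 0.14) for the IDs in the order given, each with an adjusted p of 0.000121 in limma's test. The intervals are exact binomial ones (Clopper-Pearson) on reads summed over the 2 libraries of each group. They cover counting error only and leave out the spread between libraries. PCR copies are not independent molecules, so even the counting error may be understated.

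**Figure D2:**
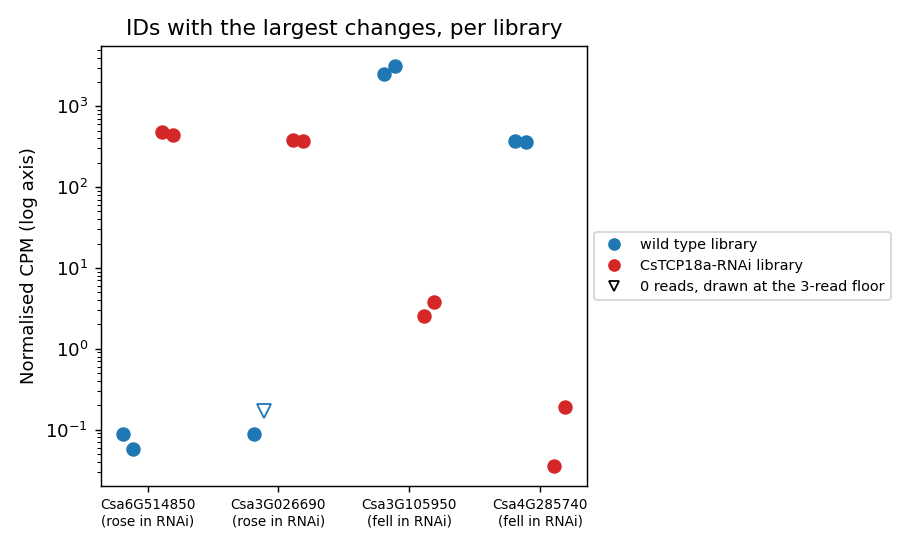
Normalised CPM (log axis) of the 4 IDs with the largest changes in each of the 4 libraries. Each point is 1 library, and the open triangle marks a library with 0 reads at its 3-read floor of 0.172. Csa6G514850 and Csa3G026690 lie between 375 and 475 (rounded) in both RNAi libraries, and Csa3G105950 and Csa4G285740 lie at 357 or above in both wild type libraries.

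Beyond these IDs, a set of genes was close to silent in one group and clearly transcribed in the other. With a mean of at least 10 normalised CPM in one group and under 0.5 in both libraries of the other, 197 genes were transcribed in the RNAi leaves and 91 in the wild type leaves. All 197 of the former and 89 of the latter passed limma's test. These passes add no support, since the genes were chosen for a large difference in the same values. Among genes with a group mean of at least 10, 27 had 0 reads in both wild type libraries and 20 had 0 reads in both RNAi libraries. A count of 0 allowed up to 0.131 and 0.172 normalised CPM in wild type replicates 1 and 2, and up to 0.107 and 0.0957 in RNAi replicates 1 and 2. These genes carried a small part of the RNA: the 91 genes made up 0.301% of the mean wild type signal and the 197 genes 0.933% of the mean RNAi signal.

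Abundant transcripts were more often lower in the RNAi leaves, and scarce transcripts more often higher. Of the 192 genes with a mean of at least 500 normalised CPM over the 4 libraries, 88 (45.8%) were lower and 21 (10.9%) were higher. Of the 1937 genes between 100 and 500, 908 (46.9%) were lower and 426 (22%) were higher. Of the 3045 genes under 5, 583 (19.1%) were lower and 1201 (39.4%) were higher. With plain CPM the genes of at least 500 kept more lower than higher calls (74 against 36), whereas the class from 100 to 500 had 625 lower and 638 higher. The 7252 genes from 20 to 100 turned from 2434 lower and 2026 higher with the deposited values to 1475 lower and 3031 higher with plain CPM. Among the 100 most abundant genes of the wild type leaves, 62 were lower in RNAi, 38 did not pass and 0 were higher. Among the 100 most abundant of the RNAi leaves, 28 were higher, 16 were lower and 56 did not pass. With plain CPM the wild type list had 55 lower and 0 higher genes, and the RNAi list 8 lower and 37 higher. The lists shared 50 genes. Choosing genes by their level in one group by itself favours a lower value in the other group.

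**Figure D3:**
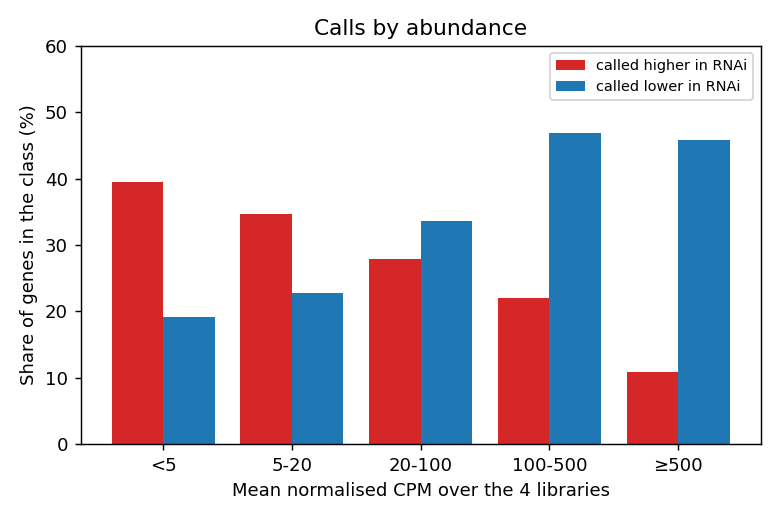
Share of genes called higher (red) or lower (blue) in RNAi leaves by limma's test, in classes of mean normalised CPM over the 4 libraries. Lower calls rise from 19.1% in the least abundant class to 45.8% in the most abundant, and higher calls fall from 39.4% to 10.9%; with plain CPM the classes from 20 to 500 no longer hold more lower than higher calls.

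The wild type libraries concentrated more of their reads in few genes. The 100 most abundant genes of each library held 25.8% and 21.4% of the reads in wild type replicates 1 and 2, against 15.4% and 16.1% in RNAi replicates 1 and 2. In the wild type libraries 778 and 993 genes sufficed for 50% of the reads, against 1469 and 1474 in the RNAi libraries. The genes called lower held 52.7% and 55.3% of the wild type reads and 22.9% and 23.7% of the RNAi reads. The genes called higher held 9.43% and 10.3% of the wild type reads and 35% and 33.8% of the RNAi reads. The direction of both shifts follows from how these genes were chosen, and the choice may also enlarge their size. At least 1 normalised CPM was reached by 16106 ± 27.6 genes in wild type and 16816 ± 41.0 genes in RNAi leaves (SD, n = 2 each). Groups of 2 cannot give an exact two-sided permutation p below 0.333, which was the value for the top-100 share and for the number of genes detected.

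**Figure D4:**
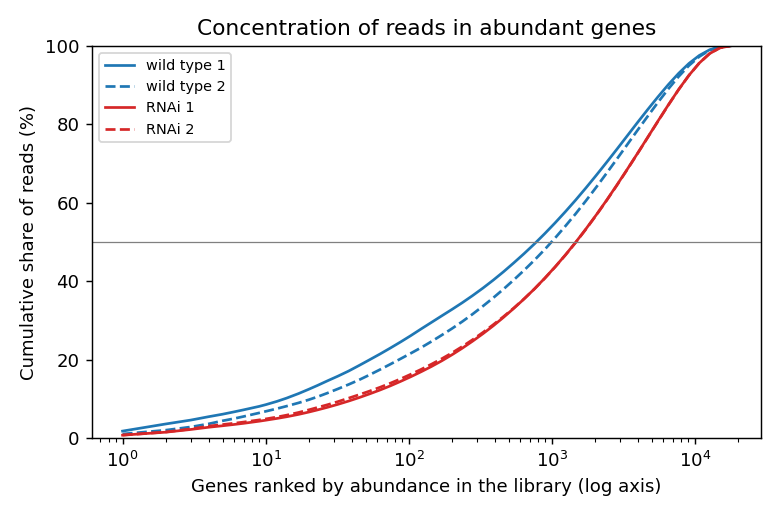
Cumulative share of reads against the number of genes, ranked by abundance within each library (log axis). The grey line marks 50%, which the wild type curves cross at 778 and 993 genes and the RNAi curves at 1469 and 1474 genes.

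The changed genes were spread over the whole gene set. The IDs carry 8 prefixes, from Csa1 to Csa7 and CsaU. In the 7 numbered prefixes the share of called genes ranged from 59.4% (Csa7) to 61.4% (Csa1), and it was 52.6% among the 78 CsaU genes. No prefix differed from the other genes in its share of calls (Fisher's exact test, two-sided, lowest adjusted p 0.756 over 8 prefixes) or in the direction of its calls (lowest adjusted p 0.791). Genes are not independent replicates in these tests.

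Libraries of the same group resembled each other far more than libraries of different groups. Across genes, Pearson's r of log2(CPM + 1) was 0.971 between the wild type libraries and 0.994 between the RNAi libraries, and it ranged from 0.688 to 0.706 between groups. Of the tested genes, 6.30% differed by more than 2-fold in CPM + 1 between the wild type libraries and 0.18% between the RNAi libraries. In the pairs across groups this share was between 38.6% and 40.8%. The biological coefficient of variation was 0.279 in wild type and 0.0905 in RNAi leaves. Counts within each group varied more than sampling allows, with a chi-square per degree of freedom of 104 in wild type and 11.4 in RNAi, so the libraries of a group were not treated as one library deposited more than once. Separate preparations from one plant would also exceed sampling noise, so this does not show that the libraries came from different plants.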

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

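Under the alternatives that kept all 4 libraries and set no fold threshold, between 9324 and 11011 genes were called, against 10592 in the main test. The 9324 came from a filter of 5 CPM, which tested only 14942 genes. The lowest count on the 17491 genes of the main test was 9624, with the replicate block. Of the genes called under an alternative and in the main test, 0 changed direction, but these fits reuse the same reads. Requiring also at least a 2-fold change of CPM + 1 left fewer, 3519 higher and 3146 lower genes. Leaving out 1 library gave between 2242 and 6295 higher and between 1854 and 6091 lower genes. The lowest counts came without RNAi replicate 1 (4096 calls, 4093 of them shared with the main test) and without RNAi replicate 2 (4423 calls, 4420 shared). The lone RNAi library is then assumed to vary like the wild type libraries, whose spread was the larger. Without wild type replicate 1 or 2 the counts rose to 12182 and 12368, by the same construction. edgeR on the recovered reads called 5202 higher and 5122 lower genes, and DESeq2 5159 and 5259. A spread estimated per group gave 5412 and 5167. The replicate block gave 4900 higher and 4724 lower genes. No label says that equal replicate numbers share a plant, batch or day, and the replicate differences of the groups correlated at -0.09 (Pearson) across genes, so the numbers were not taken as pairs. Plain CPM moved the share of higher calls from 51.2% to 68.4%. TMM applied again to the deposited values moved them by at most 0.0101 log2 units and is hardly a test. The 4 named IDs kept their direction and passed under each alternative that tested them. This adds no support, since they were chosen for the largest changes in the same reads. The size of the change moved with the pseudocount and the model (for Csa6G514850 from 6.81 to 12.57, and for Csa4G285740 from -6.48 to -11.60). Csa3G105950 is among the 100 most abundant genes and has no value without these. The planned gene lists and CsTCP18a have no alternatives, since no IDs could be paired with names. Depth limits the near-silent genes, whose ratios rest on a few reads.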

Other observations

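The mislabelling test and the test of label fields were chosen after the result was seen; plain CPM, thinning and removal of abundant genes were added after the main count was known, but their outcomes were not. The pattern of neighbouring IDs was noticed among the most changed genes and then tested on the same data. Genes with consecutive IDs changed together. Over 11987 pairs of tested genes whose ID numbers differ by 10, the fold changes correlated at 0.131 (Pearson, across genes). The highest value in 100000 permutations of genes within prefixes was 0.0419 (permutation p = 1e-05, the smallest they can give). This argues against chance order, with the limit that the pattern was noticed in the same fold changes. The permutations did not hold the abundance of the genes fixed. In 4543 of these pairs both genes were called, and 57.9% of those went the same way. The correlation was 0.052 at 2 ID steps, -0.0053 at 5 steps and -0.0026 at 10 steps. Reads shared between overlapping neighbours would keep the correlation to consecutive IDs, and the 0.052 at 2 steps was not compared with permutations. Reads shared between tandem copies may give a short reach. Joint control of neighbours or of gene clusters may give it too, and the table holds neither coordinates nor sequences to separate these. The files do not state that ID numbers follow chromosome order.

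The most prominent pattern is the extent of the difference: 10592 of 17491 genes were called and correlations across groups did not exceed 0.706. Unequal depth is argued against as its whole cause, since 10504 genes were called after thinning each library to 18930131 reads. Total calls say little about scaling, since a shift trades lower for higher calls (10583 under median-of-ratios scaling, 11011 with plain CPM). A wrong library factor would move all genes of that library the same way. Yet calls went both ways, with 5347 higher and 5236 lower under median-of-ratios scaling and 7534 and 3477 with plain CPM. This argues against scaling as the whole cause. Without the 100 most abundant genes, 10530 genes were called. That count followed a new TMM scaling, which already offsets reads taken by a few genes, so it cannot decide. One mislabelled library is argued against too, since the lowest correlation within a group exceeded the highest between groups by 0.265. Reduced CsTCP18a RNA and a difference in batch, growth or leaf stage that follows the groups cannot be told apart: 0 labelled characteristics other than genotype differ between the libraries, and 0 IDs carry a name by which the targeted gene could be read. A hypothesis for follow-up is that part of the difference may come from leaves sampled at different stages or in different batches, which markers of leaf age on named genes would address.

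The wild type libraries differed from each other more than the RNAi libraries did. Lower depth of a wild type library is argued against by the biological coefficient of variation, which leaves out counting noise and so hardly depends on depth. It was 0.279 in wild type and 0.0905 in RNAi. After thinning to equal reads it was 3.19 times as high in wild type (0.277 against 0.0867). Thinning could hardly have changed this measure, so it adds little. A placement of the wild type leaves at different points along the difference between the groups is argued against when all genes weigh the same. Over 14446 genes with a mean of at least 5 normalised CPM, the wild type replicate difference correlated with the group difference at 0.0045. Within 10 equal classes of abundance this correlation lay between -0.0623 and 0.0408. Yet in the concentration of reads wild type replicate 2 lay between wild type replicate 1 and the RNAi libraries. Its 100 most abundant genes held 21.4% of its reads, against 25.8% in wild type replicate 1 and 15.4% and 16.1% in RNAi. For the few most abundant genes such a placement therefore stays open. The RNAi replicate difference correlated with the group difference at 0.164 over the same 14446 genes. A placement of the RNAi leaves at different points along the group difference stays open, and no explanation was tested. Differences between single leaves, their handling, or RNAi libraries that share more of their origin than the wild type libraries do stay open and were not tested. Because the test pools the spread of both groups, this imbalance sets how the number of calls responds to leaving out a library.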
